A study of Mus musculus with 4 samples.

How the data were processed

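Gene expression was measured by bulk RNA-seq in 4 libraries of MC38 tumor cells, 2 from tumors labelled non-responder and 2 from tumors labelled responder, with the group and replicate number taken from the sample titles. Per the labels' protocols, RNA was captured with oligo-dT beads, and libraries were made with the KAPA mRNA HyperPrep kit, which keeps strand information. STAR is named as the aligner in the submitters' processing notes, with mm10 (GRCm38) as the build; the version and settings of STAR are not given in the sources used here. Reads were counted per gene with featureCounts 1.6.1, reverse-stranded (setting 2), on the Ensembl release 91 annotation, per the file headers. The deposited values are raw counts with no normalization, 1 file per library and not pooled.

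The counting command named in the file headers did not ask for multi-mapping reads, so reads that fit several places equally well are not in the counts. Genes with near-identical copies, such as ribosomal protein genes with pseudogenes and the mitochondrial genes that have nuclear copies, can therefore be undercounted, and reads that overlap 2 genes on a strand were not assigned. The files hold 53379 Ensembl gene identifiers, 53274 of which matched a symbol in the gene name table, and every row names a gene. Where several identifiers had 1 symbol, the identifier with the most reads was used for the lists.

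Total counts per library were 18447041 to 21754063. No 2 libraries were near-identical: the chi-square per degree of freedom between libraries ran from 24.8 to 74.1, and Pearson's correlation of log2 CPM across genes from 0.967 to 0.983 (genes are not independent replicates).

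The comparison was fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 13792, libraries were scaled by TMM (factors 0.952 to 1.036), and a robust quasi-likelihood test was run on all 4 libraries with the group as the only term. The common biological coefficient of variation was 0.216. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the standard error was taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalised and cover all genes.

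Before the data were examined, 32 gene lists were fixed: class I and class II antigen presentation, interferon gamma and type I interferon response, checkpoint ligands and immune evasion, myeloid-attracting chemokines and cytokines, NF-kB targets, cell cycle and mitosis, DNA replication and E2F targets, p53 targets, hypoxia, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, unfolded protein and integrated stress response, TGF-beta targets, epithelial to mesenchymal genes, Wnt targets, Myc targets and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, immediate early genes of tissue dissociation, and markers of leukocytes, macrophages and monocytes, neutrophils, dendritic cells, T and NK cells, B and plasma cells, fibroblasts, endothelium, skin with muscle, fat and red cells, and sex-linked genes. Lists with at least 2 tested members, 31 in all, were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes; fry tests whether its genes move one way on balance.

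Named genes followed a rule fixed in advance. It asked for the largest and most significant changes among genes past the threshold; as no gene passed, it took the 12 genes of smallest p in each direction with a mean of at least 5 CPM, leaving out predicted genes, plus the member of smallest p in each list and 15 genes set beforehand (among them Ptprc, B2m, H2-K1, H2-D1, Irf1, Cd274, Ifngr1, Jak1, Jak2, Mki67, Csf1, Cxcl9, Cxcl10 and Arg1). Some of the genes that the rule takes are not reported here. Other members of the lists, and the gene families in the closing part, were named after their values were seen.

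Alternatives set beforehand were RLE and upper-quartile factors and library size alone in place of TMM, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter of 5 CPM in 2 libraries, mitochondrially encoded genes left out, the replicate number as a block, each library left out in turn, an estimated correlation for the lists, and the unadjusted p. Where a left-out library leaves 1 library in its group, that library is assumed to vary like the other group. Fits with the mean leukocyte marker level or the Xist level as a covariate, and with each library's trend on GC content and transcript length removed, were added after seeing the data, as were the list tests under upper-quartile factors, library size alone, no filter and no mitochondrially encoded genes. GC content and length were known for 99.9% of tested genes, and the trends explained 0.475% to 8.79% of the variance of a library's deviations.

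The test was tested on simulated data made from the means, spread and library sizes of this comparison. With 50 genes changed at each fold, edgeR called 27 of 50 at 2-fold and 50 of 50 at 4-fold, 8-fold and 16-fold among 13493 genes, and 23 of 13263 unchanged genes. A list shifted 1.4-fold was called (camera adjusted p = 9.66e-09) and 0 of 30 unchanged lists were called. These simulated genes vary independently of each other, unlike the real libraries, so the shares called need not hold for the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.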

Results

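Tumor cells were profiled from subcutaneous MC38 tumors in C57BL/6 mice that had received a sub-optimal course of anti-PD-1, an antibody that blocks the inhibitory receptor PD-1 on T cells. MC38 is a mouse colon adenocarcinoma line, here carrying GFP, and each mouse was inoculated with 50000 cells. Each dose was 100 µg of antibody, the first on day 12, with the others following on day 15, day 18 and day 22. Malignant cells were sorted from tumors labelled as responders and as non-responders, and their polyadenylated RNA was sequenced in bulk. The labels do not say how or on which day response was scored. The comparison asks how the malignant cells of the tumors so labelled differ. There were 2 libraries per group. Total counts were 21754063 and 21670040 in non-responder replicates 1 and 2, and 20458601 and 18447041 in responder replicates 1 and 2. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. All fold changes are responder relative to non-responder, and CPM values are means ± SD with n = 2 per group.

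Among the genes of smallest p, none of which passed edgeR's test over all genes, several that encode matrix or adhesion proteins were lower in responder tumor cells. Pcdh10, a protocadherin adhesion molecule, had 51.1 ± 11.5 CPM in non-responder and 14.1 ± 0.61 CPM in responder libraries, 3.63-fold lower (log2 fold change -1.86, SE 0.21). Cilp, a cartilage matrix protein, was 5.02-fold lower (411 ± 173 against 81.8 ± 10.3 CPM), and Mfap4, a microfibril-associated glycoprotein, was 6.15-fold lower (57.5 ± 2.58 against 9.32 ± 4.51 CPM). The log2 fold change of Mfap4 was -2.62. It was -3.23 without responder replicate 1 and -2.20 without responder replicate 2. Emilin1, an elastic-fiber glycoprotein, was 2.59-fold lower (75.7 ± 5.05 against 29.3 ± 5.43 CPM), and the collagen chain gene Col1a1 was 2.53-fold lower (259 ± 26.9 against 103 ± 13.8 CPM). In the other direction, Iqcn had 0.87 ± 0.48 CPM in non-responder and 13.0 ± 2.92 CPM in responder libraries, 14.7-fold higher. Its log2 fold change of 3.88 was 4.59 without non-responder replicate 2 and 3.42 without non-responder replicate 1. The orphan nuclear receptor gene Nr4a1 was 2.40-fold higher (29.8 ± 2.19 against 71.6 ± 6.46 CPM) and Polg2, the accessory subunit of the mitochondrial DNA polymerase, was 2.92-fold higher (8.15 ± 2.50 against 23.8 ± 0.49 CPM).

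The remaining leading genes that were lower in responders included Olfml3 (3.39-fold), Syt13 (3.64-fold), C1qtnf3 (3.81-fold), the guanine nucleotide exchange factor gene Arhgef6 (3.26-fold), the pro-apoptotic BH3-only gene Bmf (2.27-fold), the secreted chaperone gene Clu (3.02-fold) and Sparcl1 (2.96-fold). Those that were higher included the neurotrophic factor gene Gdnf (1.77-fold), the Hippo-pathway transcription factor gene Tead4 (1.80-fold), the NF-kB inhibitor gene Nfkbia (1.94-fold), the Wnt ligand gene Wnt7b (1.83-fold), Tex19.1 (3.08-fold), Egr1 (2.44-fold), Egr2 (2.67-fold) and Mybl2 (1.65-fold). In each of the leading genes named here both responder libraries lay on the same side of both non-responder libraries. On the mm10 build, Pcdh10 (ENSMUSG00000049100) spans chromosome 3 from 45378398 to 45435623, Cilp (ENSMUSG00000042254) chromosome 9 from 65265180 to 65280605, Iqcn (ENSMUSG00000110622) chromosome 8 from 70703457 to 70717650, and Nr4a1 (ENSMUSG00000023034) chromosome 15 from 101266846 to 101274792, with counts taken over the annotated exons.

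**Figure D1:**
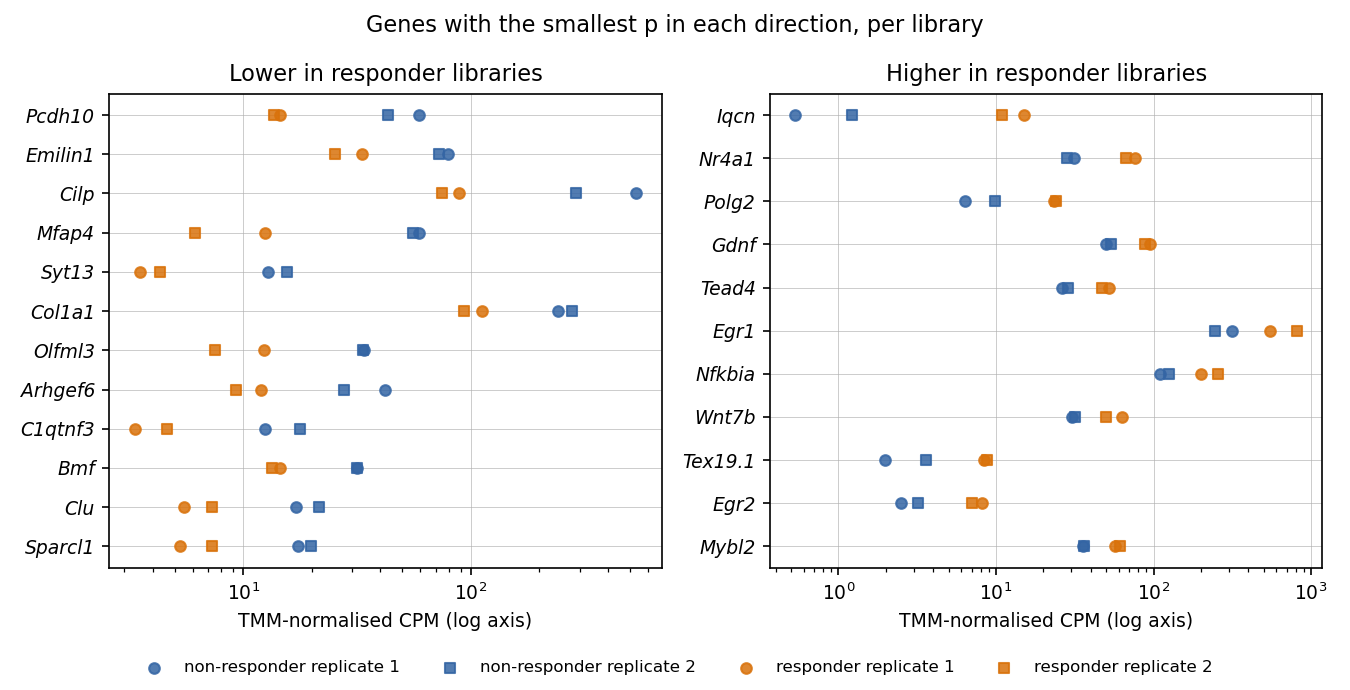
Normalised expression, in TMM-normalised CPM on a log axis, of 12 lower and 11 higher genes from among those of smallest p in each direction with a mean of at least 5 CPM; each point is 1 library, blue for non-responder and orange for responder, with circles for replicate 1 and squares for replicate 2. For Pcdh10 the non-responder libraries sit at 59.2 and 43.0 CPM and the responder libraries at 14.5 and 13.6 CPM, while for Nr4a1 they sit at 31.4 and 28.3 against 76.2 and 67.1 CPM.

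No single gene passed the test. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 13792 genes, 0 genes passed an adjusted p of 0.05 and the smallest adjusted p was 0.111. At an unadjusted p under 0.05 there were 856 genes, 355 higher and 501 lower, where chance gives 690 on average. The other divisions of these libraries into equal groups gave 1081 and 160 genes, so 856 is not an excess over them. DESeq2 called 64 genes, 15 higher and 49 lower, among them Iqcn, Mfap4, Cilp, Pcdh10 and Col1a1, and limma-voom called 0 (875 at an unadjusted p under 0.05). Groups did not overlap for 5035 genes, 36.5% of those tested, where chance gives 33.3%. Every fit with 1 library left out called more genes than the full fit: 41 without non-responder replicate 1, 516 without non-responder replicate 2, 67 without responder replicate 1 and 173 without responder replicate 2. Pcdh10, Emilin1, Cilp, Postn, Dpt, Nid2, Arhgef6, Ighm, Iqcn, Nr4a1 and Polg2 were called in all of these fits. The fits share libraries and each leaves 1 library in a group, so shared calls are not replication.

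Fibroblast markers were lower in responder tumor cells as a group. Of 19 tested members, 16 were lower and 3 higher, with a median log2 fold change of -0.67, or 1.59-fold lower. Postn (periostin) had 127 and 57.8 CPM in the non-responder libraries and 16.8 and 19.1 CPM in the responder libraries. Dpt (dermatopontin) had 67.6 and 101 against 37.3 and 29.0 CPM, the platelet-derived growth factor receptor gene Pdgfrb 221 and 198 against 107 and 78.4 CPM, and Fap 10.0 and 13.7 against 4.67 and 5.29 CPM. Other abundant members went another way: Col6a3 had a log2 fold change of 0.05 and Col1a2 of 0.24, the latter with 126 CPM in responder replicate 1 and 20.3 CPM in responder replicate 2. The list passed the set test (camera adjusted p = 9.46e-16 with a preset correlation of 0.01) but had an adjusted p = 0.438 with an estimated correlation. No member passed over all genes tested and 8 passed when adjusted over the list alone. Transcripts of leukocytes and Xist, which can mark cells of the mouse rather than the tumor, were also lower on average in responder libraries: Xist had 7.83 and 17.1 CPM in non-responder and 1.39 and 8.60 CPM in responder replicates 1 and 2.

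The epithelial to mesenchymal list had 13 of 18 members lower at a median of -0.17 and did not pass (camera adjusted p = 0.0645). The median was -0.05 without non-responder replicate 1, -0.34 without non-responder replicate 2, -0.29 without responder replicate 1 and -0.06 without responder replicate 2. Mmp2, a gelatinase, had 552 ± 76.6 CPM in non-responder and 327 ± 13.7 CPM in responder libraries (log2 fold change -0.75, SE 0.20), while Epcam and the keratin genes Krt8, Krt18 and Krt19 were too low to be tested. TGF-beta targets went both ways, 8 higher and 11 lower of 19 (camera adjusted p = 0.85). Camera's direction for that list turned from lower to higher without non-responder replicate 1 or responder replicate 2 (adjusted p = 0.387 and 0.494).

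Immediate early genes, which are also induced while tissue is dissociated, were higher in responder tumor cells. Of 25 tested members 23 were higher, with a median log2 fold change of 0.76 (camera adjusted p = 4.43e-20, and adjusted p = 0.438 with an estimated correlation). Egr1 had 316 and 244 CPM in non-responder and 550 and 817 CPM in responder libraries, and Egr2 2.51 and 3.19 against 8.19 and 7.08 CPM. The heat-shock gene Hspa1b had 20.1 and 30.8 against 61.7 and 157 CPM, and the anti-proliferative gene Btg2 10.9 and 11.0 against 15.6 and 28.6 CPM. Several members were high in responder replicate 2 alone: Fos had 608 CPM there against 213, 204 and 240 CPM in the other libraries, and Fosb had 701 against 222, 172 and 211 CPM. No member passed over all genes tested and 9 passed when adjusted over the list alone. Without responder replicate 2 the list median was 0.36, with the call kept (camera adjusted p = 3.49e-09).

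Genes of DNA replication were slightly and uniformly higher in responder tumor cells. All 30 tested members of the DNA replication and E2F list were higher, 28 of them with groups that did not overlap, where chance gives 33.3% of genes over both directions, at a median log2 fold change of 0.42 (camera adjusted p = 4.67e-16, and adjusted p = 0.438 with an estimated correlation). Chek1, a replication checkpoint kinase, had 27.7 ± 1.78 and 42.9 ± 1.48 CPM (log2 fold change 0.63, SE 0.17), and the replicative helicase gene Mcm5 102 and 120 against 159 and 174 CPM. The cell cycle and mitosis list had 21 of 28 members higher at a smaller median of 0.12 (camera adjusted p = 0.00294, and adjusted p = 0.646 with an estimated correlation). That call was lost without non-responder replicate 2 (camera adjusted p = 0.439) or responder replicate 2 (camera adjusted p = 0.479), with medians of 0.06 and -0.02. The median was 0.23 without non-responder replicate 1 and 0.31 without responder replicate 1. The proliferation marker Mki67 had 584 ± 172 and 571 ± 35.8 CPM. Its log2 fold change of -0.03 was 0.31 without non-responder replicate 1 and 0.02 without responder replicate 1. Cyclin D1 (Ccnd1), listed among Wnt targets, had 535 ± 5.35 and 803 ± 19.5 CPM. Wnt targets as a list had 8 of 12 members higher and did not pass (camera adjusted p = 0.188) except without non-responder replicate 1 (camera adjusted p = 0.0333). The p53 targets, 11 of 19 higher, did not pass either (camera adjusted p = 0.499).

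Of 26 Myc and ribosome biogenesis genes 25 were higher in responder libraries, at a median log2 fold change of 0.37 (camera adjusted p = 5.06e-09, and adjusted p = 0.438 with an estimated correlation). Rrp9, a factor for processing of ribosomal RNA, had 26.6 ± 4.34 and 43.1 ± 5.53 CPM, and Myc itself had 173 and 121 against 199 and 185 CPM. Without non-responder replicate 2 the median of that list was 0.19 (camera adjusted p = 0.0107). Cytosolic ribosomal protein genes were higher in 27 of 33 members at a median of 0.29 (camera adjusted p = 4.76e-05, and adjusted p = 0.646 with an estimated correlation). This call was lost without non-responder replicate 1 (camera adjusted p = 0.0561) or responder replicate 2 (camera adjusted p = 0.0732), with medians of 0.12 and 0.13, and the median was 0.47 without non-responder replicate 2. Genes of this kind can share reads with pseudogenes. Rps6 and Rps16 were counted at 1.21 and 0.58 CPM in non-responder replicate 1. Rpl3, the member of smallest p, had a log2 fold change of 0.74, which was 0.31 without responder replicate 2.

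**Figure D2:**
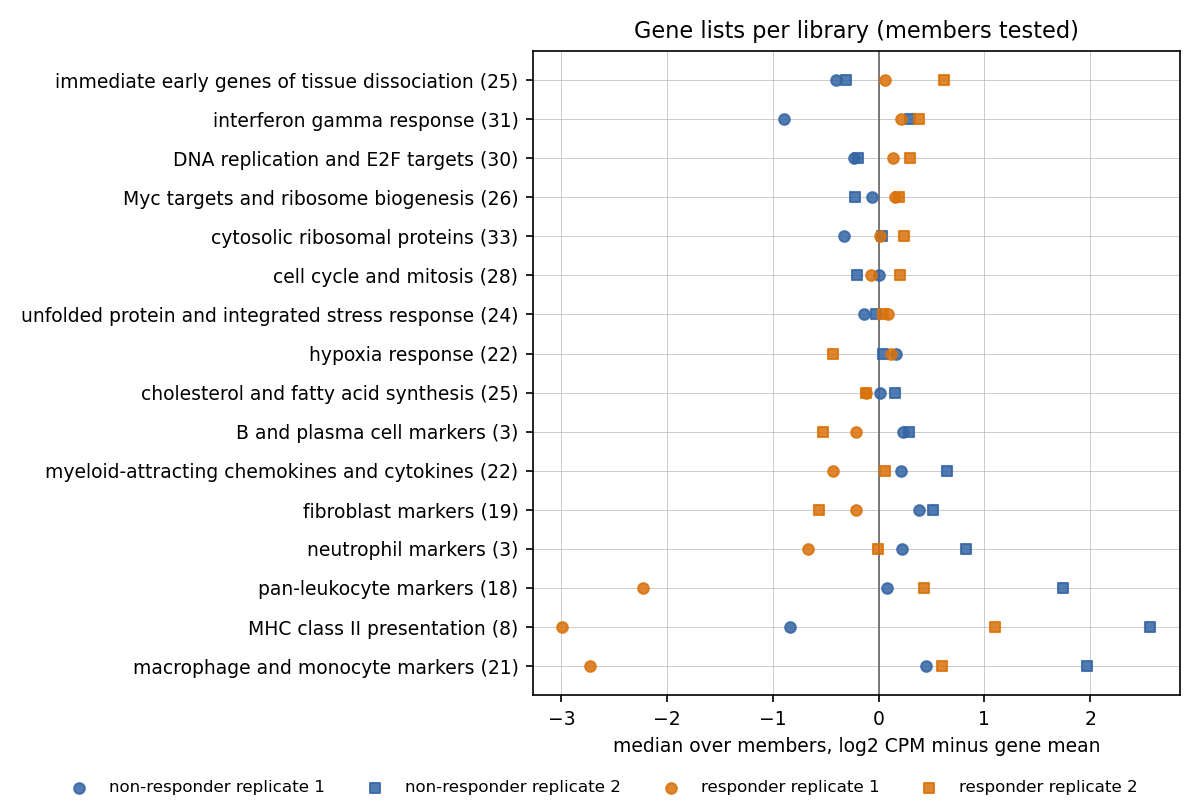
Per-library level of the 16 gene lists that passed the set test with a preset correlation; the horizontal axis gives the median over members of log2 CPM minus the gene's mean over the 4 libraries, and the number of members tested stands after each name. Fibroblast markers sit at 0.38 and 0.52 in non-responder and -0.21 and -0.57 in responder libraries, whereas interferon gamma response genes stand apart at -0.89 in non-responder replicate 1.

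Interferon gamma response genes were low in 1 library, non-responder replicate 1, and alike in the other libraries. The guanylate-binding protein gene Gbp2 had 488 CPM there, against 1180 CPM in non-responder replicate 2 and 1470 and 1430 CPM in the responder libraries, and Cd274, which encodes the PD-1 ligand PD-L1, had 36.6 against 101, 114 and 130 CPM. As a list, 24 of 31 members were higher in responders at a median log2 fold change of 0.43 (camera adjusted p = 5.32e-05, and adjusted p = 0.646 with an estimated correlation). Without non-responder replicate 1 the direction turned and the call was lost (median -0.03, camera adjusted p = 0.669), and without non-responder replicate 2 the median was 1.22 (camera adjusted p = 8.07e-40). The chemokine genes Cxcl10 and Cxcl9 had 242 ± 115 and 75.1 ± 83.9 CPM in non-responder and 392 ± 17.4 and 59.9 ± 23.4 CPM in responder libraries, and Gbp7 331 ± 141 and 540 ± 27.1 CPM. Irf1 had 374 ± 123 and 430 ± 34.3 CPM. The log2 fold change of Irf1 turned from 0.20 to -0.09 without non-responder replicate 1. That of Cxcl9 turned from -0.33 to 1.92 without non-responder replicate 2 and to 0.03 without responder replicate 2. The receptor and kinase genes Ifngr1, Jak1 and Jak2 had log2 fold changes of -0.23 (SE 0.20), -0.18 (SE 0.21) and -0.20 (SE 0.17), and that of Ifngr1 was 0.02 without non-responder replicate 2. Without responder replicate 2 those of Jak1 and Jak2 were -0.03 and -0.07.

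Class I antigen presentation followed the same library. The class I heavy chain gene H2-K1 had 895 CPM in non-responder replicate 1 against 1970, 1640 and 1600 CPM, and H2-D1 had 636 against 1470, 1220 and 1190 CPM. B2m, the class I light chain, had 4985 ± 441 and 5575 ± 77.6 CPM, and H2-Q7 193 ± 98.3 and 265 ± 16.7 CPM. The class I list had 16 of 23 members higher at a median of 0.12 and did not pass (camera adjusted p = 0.178). It passed as higher without non-responder replicate 2 (median 0.72, camera adjusted p = 8.79e-13) and as lower without non-responder replicate 1 (median -0.23, camera adjusted p = 0.00241), where H2-K1 and H2-D1 both had a log2 fold change of -0.28. Type I interferon response genes had a median of -0.06 but a mean of 0.01 over 32 members (camera adjusted p = 0.85); Ifnar1, a receptor subunit, had 107 ± 1.28 and 83.1 ± 1.15 CPM. Left out singly, non-responder replicate 1 turned that list lower (median -0.26, camera adjusted p = 1.25e-06) and non-responder replicate 2 made it pass as higher (median 0.44, camera adjusted p = 1.98e-08). Without responder replicate 2 it turned lower and did not pass (median -0.13, camera adjusted p = 0.741).

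Checkpoint ligand and immune evasion genes had 11 of 15 members lower and did not pass (median -0.27, camera adjusted p = 0.152). It passed as lower without non-responder replicate 1 (median -0.49, camera adjusted p = 0.015) or responder replicate 2 (median -0.15, camera adjusted p = 0.000717). It turned higher without non-responder replicate 2 (median 0.075, camera adjusted p = 0.409). NF-kB targets had 11 of 19 members higher (camera adjusted p = 0.212), with Nfkbia passing when adjusted over the list alone.

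Leukocyte transcripts were scarce in the sorted tumor cells and differed widely within each group. Ptprc, which encodes CD45, the marker of the immune fraction sorted separately, had 5.95 and 22.6 CPM in non-responder and 0.65 and 6.92 CPM in responder replicates 1 and 2. The macrophage genes C1qa and Lyz2 had 10.6 and 20.1 CPM in non-responder replicate 1, 38.5 and 41.7 CPM in non-responder replicate 2, 1.04 and 0.94 CPM in responder replicate 1, and 13.7 and 13.2 CPM in responder replicate 2. All 18 pan-leukocyte markers were lower on average in responders (median -1.50, camera adjusted p = 1.65e-07), as were 20 of 21 macrophage and monocyte markers (median -1.74, camera adjusted p = 6.05e-08), with Spp1 the exception. Both lists had an adjusted p = 0.646 with an estimated correlation and both calls were lost without non-responder replicate 2 (camera adjusted p = 0.189 and 0.173), with medians of -0.49 and -0.81, while without responder replicate 2 the medians were -3.79 and -4.95. Without responder replicate 1 they were -0.71 and -0.94. The chemokine receptor gene Ccr2 had 3.40 ± 1.86 and 0.55 ± 0.63 CPM, Arhgdib 15.8 ± 4.71 and 9.67 ± 0.27 CPM, Cd86 2.14 ± 1.73 and 0.47 ± 0.45 CPM, and the arginase gene Arg1 4.13 ± 1.4 and 1.70 ± 1.98 CPM.

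Class II presentation genes were lower in 8 of 8 members (median -1.63, camera adjusted p = 0.0324, and adjusted p = 0.646 with an estimated correlation) and had the same order of libraries, with summed CPM of 48.2 and 462 in non-responder and 11.5 and 155 in responder replicates. H2-DMb1 had 6.89 ± 3.53 and 4.26 ± 0.20 CPM. The class II call was lost without responder replicate 1 (camera adjusted p = 0.463), and without non-responder replicate 2 the direction turned (camera adjusted p = 0.798). Its median was -0.70 without responder replicate 1, 0.93 without non-responder replicate 2 and -5.22 without responder replicate 2. In fits added after the results were seen it was 1.08 with the leukocyte covariate (camera adjusted p = 0.00186) and 0.96 with the Xist covariate (camera adjusted p = 0.123). Neutrophil markers were lower in 3 of 3 tested members (median -0.69, camera adjusted p = 0.022, and adjusted p = 0.646 with an estimated correlation). Mmp9, the 1 member of that list with a mean of at least 5 CPM, had 369 ± 39.2 and 236 ± 74.8 CPM. S100a8, S100a9 and Ly6g were too low to be tested. That call was lost without non-responder replicate 2 (camera adjusted p = 0.382) or responder replicate 1 (camera adjusted p = 0.18). The median was -1.22 without non-responder replicate 1 and -2.09 without responder replicate 2. Dendritic cell markers went both ways (3 higher and 2 lower, median 0.01 and mean -0.48, camera direction lower, camera adjusted p = 0.725), with Irf8 at 2.51 ± 1.84 and 0.96 ± 1.08 CPM, and passed as lower without responder replicate 2 (median -0.68, camera adjusted p = 0.00362). Their camera direction turned higher without non-responder replicate 2 (adjusted p = 0.111) or responder replicate 1 (adjusted p = 0.588). T and NK cell markers were nearly all too low to be tested. The 4 tested did not pass (median -0.37, camera direction higher, adjusted p = 0.591). Their direction turned lower without non-responder replicate 1 or responder replicate 2 (camera adjusted p = 0.0737 and 0.273), with medians of -1.29 and -1.68. The median was 0.72 without non-responder replicate 2 and -0.04 without responder replicate 1. Lag3 had 1.08 ± 0.57 and 3.03 ± 0.28 CPM.

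**Figure D3:**
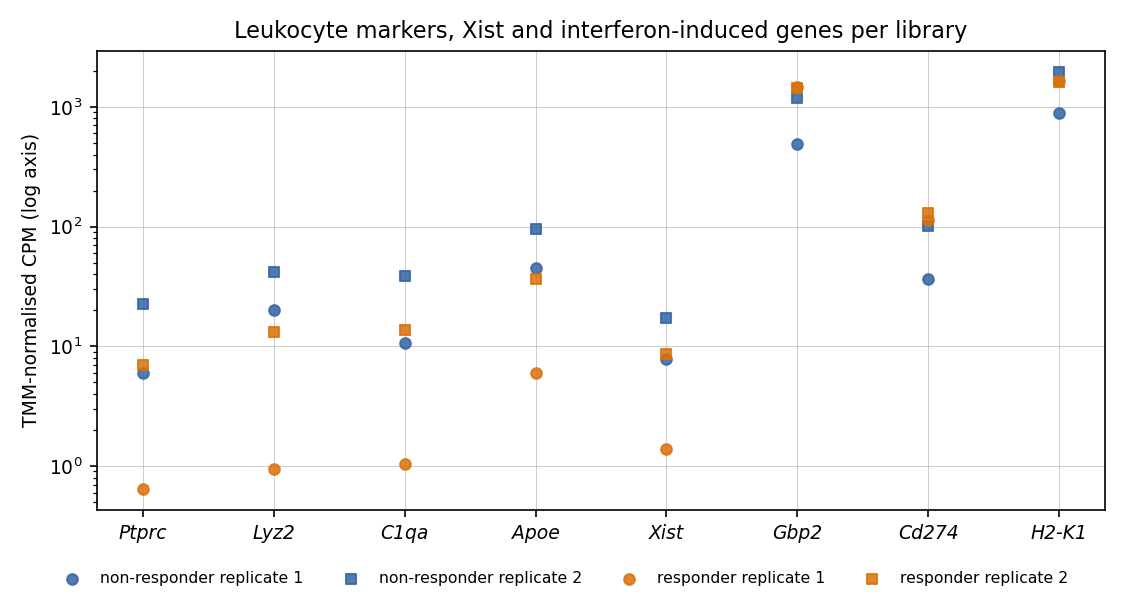
TMM-normalised CPM on a log axis of 4 leukocyte genes, Xist, and 3 interferon-induced genes; each point is 1 library, blue for non-responder and orange for responder, with circles for replicate 1 and squares for replicate 2. Ptprc is highest in non-responder replicate 2 at 22.6 CPM and lowest in responder replicate 1 at 0.65 CPM, whereas Gbp2 is lowest in non-responder replicate 1 at 488 CPM.

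Chemokines and cytokines that attract or sustain myeloid cells were lower in 16 of 22 tested members (median -0.58, camera adjusted p = 0.000482, and adjusted p = 0.575 with an estimated correlation). Scarce members were among those lower: Cxcl5, a neutrophil-attracting chemokine, had 1.98 ± 1.09 and 0.13 ± 0.10 CPM, and Ccl12 1.45 and 1.53 against 0.15 and 0.42 CPM. Of the abundant members Csf1, the macrophage growth factor, had 330 ± 21.0 and 369 ± 20.2 CPM and Il34 had 56.6 and 96.0 against 85.5 and 87.2 CPM. No member passed over all genes tested and 2 passed when adjusted over the list alone, and the call was lost without non-responder replicate 2 (camera adjusted p = 0.409) or responder replicate 1 (camera adjusted p = 0.0579), with medians of -0.31 and -0.25, while without responder replicate 2 the median was -2.49. Leukocyte markers fell with this list. In fits added after the results were seen, its median was -0.07 with the leukocyte covariate (camera adjusted p = 0.369) and -0.01 with the Xist covariate (camera adjusted p = 0.411). With genes under 5 CPM left out the list turned higher and did not pass (camera adjusted p = 0.4).

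B and plasma cell markers passed on 3 tested members (median -0.32, camera adjusted p = 0.000619, and adjusted p = 0.438 with an estimated correlation) through Ighm alone, the 1 member that passed when adjusted over the list alone. Ighm, the immunoglobulin mu constant region, had 9.48 and 5.39 CPM in non-responder and 0.30 and 0.42 CPM in responder libraries, 20.4-fold lower (SE 0.48 on a log2 fold change of -4.35). The light chain gene Igkc had at most 0.44 CPM in any library, so it is open whether the Ighm reads came from B cells. The call was lost without non-responder replicate 1 (camera adjusted p = 0.0721) or responder replicate 2 (camera adjusted p = 0.175). The median was -0.18 without non-responder replicate 1, -0.08 without non-responder replicate 2 and -0.52 without responder replicate 1. Endothelial markers did not pass (4 of 6 lower, camera adjusted p = 0.188), although Pecam1 (CD31) had 21.7 ± 5.42 and 9.0 ± 3.74 CPM and passed when adjusted over the list alone. Skin, muscle, fat and red cell markers did not pass (4 of 7 higher with a median of 0.17 and a mean of -0.05, camera direction higher, adjusted p = 0.905). Their direction was lower without responder replicate 1 (median 0.10, camera adjusted p = 0.882), and the median was 0.43 without non-responder replicate 1. The troponin gene Tnnt3 had 0.92 ± 0.55 and 0.49 ± 0.20 CPM. The Y-linked genes had at most 0.145 CPM in any library, and Xist had 12.4 ± 6.53 and 4.99 ± 5.10 CPM (log2 fold change -1.32, SE 0.98). That of Xist was -3.16 without responder replicate 2, -0.53 without responder replicate 1 and -0.66 without non-responder replicate 2.

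Metabolic lists differed modestly. Cholesterol and fatty acid synthesis genes were lower in 19 of 25 members (median -0.26, camera adjusted p = 0.00273, and adjusted p = 0.575 with an estimated correlation). Hmgcs1, an early enzyme of the mevalonate pathway, had 169 ± 23.6 and 111 ± 7.01 CPM, and the sterol demethylase gene Cyp51 193 and 134 against 113 and 104 CPM, while the fatty acid synthase gene Fasn had 412 and 554 against 660 and 637 CPM. The call was lost without non-responder replicate 2 (camera adjusted p = 0.126) or responder replicate 2 (camera adjusted p = 0.0604). Hypoxia response genes were lower in 18 of 22 members (median -0.24, camera adjusted p = 0.00494, and adjusted p = 0.646 with an estimated correlation), through responder replicate 2. Ero1l had 595 CPM in that library against 1050, 961 and 1080 CPM, and Pfkfb3, a regulator of glycolysis, had 28.4 ± 2.96 and 17.2 ± 1.64 CPM. Without responder replicate 2 the hypoxia list turned higher (median 0.02, camera adjusted p = 0.205), and without non-responder replicate 1 its call was lost (median -0.15, camera adjusted p = 0.167), while without responder replicate 1 the median was -0.62.

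The unfolded protein and integrated stress response list had 15 of 24 members higher at a median of 0.10 and passed narrowly (camera adjusted p = 0.0498, and adjusted p = 0.575 with an estimated correlation). The members that were higher included the serine synthesis gene Psat1, at 402 ± 42.0 and 589 ± 27.2 CPM. The endoplasmic reticulum chaperone gene Hspa5 had 1410 and 1390 against 1390 and 1220 CPM. That call was lost whichever library was left out (camera adjusted p = 0.0756 to 0.188), with medians of 0.22 without non-responder replicate 2 and 0.17 without responder replicate 2. Glycolysis genes (9 higher and 11 lower, camera adjusted p = 0.905; Hk2 at 262 ± 6.68 and 193 ± 41.7 CPM) and oxidative phosphorylation genes (17 higher and 13 lower, camera adjusted p = 0.725; Cyc1 at 90.9 ± 32.3 and 127 ± 12.0 CPM) did not pass. The direction of each turned in 2 of the 4 fits with 1 library left out. Glycolysis turned higher without non-responder replicate 2 or responder replicate 2 (camera adjusted p = 0.381 and 0.178). Oxidative phosphorylation turned lower without non-responder replicate 1 or responder replicate 2 (camera adjusted p = 0.592 and 0.929). Mitochondrially encoded genes took 5.61% and 3.07% of counts in non-responder and 3.27% and 4.22% in responder replicates 1 and 2. As a list they did not pass (6 of 7 lower, camera adjusted p = 0.292), with mt-Nd5 at 5857 ± 3580 and 3908 ± 436 CPM, its log2 fold change turning from -0.58 to 0.24 without non-responder replicate 1. Left out singly, non-responder replicate 1 turned that list higher (camera adjusted p = 0.00519), while non-responder replicate 2 (camera adjusted p = 3.73e-06) and responder replicate 2 (camera adjusted p = 0.0331) made it pass as lower. The 50 most abundant genes took 15.9% and 14.0% of counts in non-responder and 13.1% and 13.6% in responder replicates.

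Of the 31 lists tested with camera, 16 passed with a preset correlation, 7 higher and 9 lower, 0 passed with an estimated correlation and 0 passed with fry. Apart from the fibroblast, immediate early, myeloid chemokine, NF-kB, B and plasma cell and endothelial lists, no tested list had a member that passed when adjusted over the list alone. The immediate early, DNA replication, Myc and ribosome biogenesis, and fibroblast lists kept both direction and call in all 4 fits that left out 1 library. With 2 libraries against 2, no exact permutation test of a single value can give a two-sided p below 0.333, so values such as the mitochondrial share are given per library without a test.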

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

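The fits with a leukocyte or Xist covariate, those with GC content and length trends removed, and the list tests under upper-quartile factors, library size alone, no filter and no mitochondrially encoded genes were chosen after the results were seen. The edgeR count of 0 genes held with RLE, upper-quartile factors, library size alone, the stricter filter, no mitochondrially encoded genes and the GC and length correction, and limma-voom gave 0. It was 64 with DESeq2 (15 higher, 49 lower), 212 without a filter (69 higher, 143 lower), 97 with the leukocyte covariate (35 higher, 62 lower), 35 with the Xist covariate (8 higher, 27 lower), 41 to 516 with 1 library left out, and 856 at an unadjusted p under 0.05. The labels tie no same-numbered libraries together, so no pairing was taken from the replicate numbers. Same-numbered libraries' deviations correlated at 0.373 across genes. With 2 pairs only, that does not settle whether they share an animal, day or batch. With the replicate block edgeR called 32 genes (6 higher, 26 lower, among the lower Cd74, Mpeg1, H2-Ab1, H2-Aa and H2-Eb1), the log2 fold change of Cxcl9 was 0.27 and skin, muscle, fat and red cell markers turned lower (camera adjusted p = 0.913). The checkpoint list then passed as lower (camera adjusted p = 0.0241). Class II, pan-leukocyte and macrophage lists stayed lower, at camera adjusted p = 1.76e-17, 3.29e-18 and 2.62e-21 with the block. With an estimated correlation camera's adjusted p was 0.438 for the DNA replication, Myc, immediate early, B cell and fibroblast lists, 0.575 for myeloid chemokines, cholesterol and the unfolded protein response, and 0.646 for class II, interferon gamma, cell cycle, hypoxia, ribosomal proteins, leukocytes, macrophages and neutrophils.

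The unfolded protein response list lost its call with RLE (camera adjusted p = 0.0529), upper-quartile factors (0.0512), no filter (0.0594), the stricter filter (0.0535), no mitochondrially encoded genes (0.0514), the leukocyte covariate (0.159), the Xist covariate (0.196) and the GC and length correction (0.155), its range over single libraries left out being 0.0756 to 0.188. Without a filter the type I interferon (camera adjusted p = 0.839) and T and NK cell lists (0.0135) turned lower. With the stricter filter class II lost its call (camera adjusted p = 0.171), and checkpoint (0.71), myeloid chemokine (0.4), glycolysis (0.759) and dendritic cell lists (0.525) turned higher; scarce members drop out there. With GC and length corrected, oxidative phosphorylation (camera adjusted p = 0.714) and skin, muscle, fat and red cell markers (0.84) turned lower. The log2 fold change of Mki67 was 0.0082 with library size alone and 0.0597 with GC and length corrected, and the log2 fold change of Cxcl9 was 0.32 with limma-voom.

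With the leukocyte covariate class II turned higher and passed (camera adjusted p = 0.00186); checkpoint (0.964) and dendritic cell lists (0.39) turned higher, skin, muscle, fat and red cell markers lower (0.789); and myeloid chemokine (0.369), cholesterol (0.115), macrophage (0.394) and neutrophil lists (0.789) lost their calls. Irf8, Ifngr1 and Cxcl9 then had log2 fold changes of 0.23, 0.0039 and 0.30. Class I (camera adjusted p = 0.00948), type I interferon (0.00047) and T and NK cell lists (0.043) passed as higher with the leukocyte covariate, and likewise with the Xist covariate (camera adjusted p = 0.0307, 0.00281 and 0.0388). With the Xist covariate class II (camera adjusted p = 0.123), checkpoint (0.999), pan-leukocyte (0.999) and dendritic cell lists (0.358) turned higher, skin, muscle, fat and red cell markers lower (0.791), and myeloid chemokine (0.411), cholesterol (0.106), macrophage (0.73) and neutrophil lists (0.791) lost their calls, while Irf8 had a log2 fold change of 0.27. Medians with the leukocyte and Xist covariates were -0.19 and -0.03 for macrophages, -0.19 and -0.25 for neutrophils, 0.95 and 0.86 for interferon gamma, 0.25 and 0.28 for cell cycle, -0.65 and -0.68 for hypoxia, and 0.51 and 0.50 for ribosomal proteins.

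With 1 library left out, camera's adjusted p ran from 8.79e-13 to 0.14 for class I, 5.87e-06 to 0.798 for class II, 8.07e-40 to 0.669 for interferon gamma, 1.98e-08 to 0.741 for type I interferon, and 0.000717 to 0.435 for checkpoint genes. It ran from 3.36e-12 to 0.409 for myeloid chemokines, 7.24e-06 to 0.479 for cell cycle and 1.44e-10 to 0.205 for hypoxia. It ran from 0.178 to 0.381 for glycolysis, 0.293 to 0.929 for oxidative phosphorylation, 0.00091 to 0.126 for cholesterol and 0.257 to 0.494 for TGF-beta targets. It ran from 3.89e-08 to 0.0732 for ribosomal proteins and 3.73e-06 to 0.882 for mitochondrially encoded genes. Among cell type markers it ran from 2.39e-45 to 0.189 for leukocytes, 2.25e-79 to 0.173 for macrophages, 4.28e-06 to 0.382 for neutrophils, 0.00362 to 0.588 for dendritic cells, 0.0737 to 0.588 for T and NK cells, 0.00159 to 0.175 for B and plasma cells, and 0.205 to 0.882 for skin, muscle, fat and red cells. Log2 fold changes ran from -0.28 to 0.92 for H2-D1, -0.28 to 0.85 for H2-K1, -0.0936 to 0.58 for Irf1, -0.43 to 0.0177 for Ifngr1, -1.16 to 1.92 for Cxcl9, -0.31 to 0.31 for Mki67 and -1.10 to 0.24 for mt-Nd5. Apart from these and Irf8, named genes kept their direction in all settings run. With 1 library left out, log2 fold changes ran from -4.45 to -0.66 for Ptprc, -5.01 to -1.77 for Ccr2, -3.80 to -0.98 for Cd86, -3.77 to -0.42 for Arg1, -5.09 to -3.19 for Cxcl5, 0.28 to 1.74 for Cd274 and 1.03 to 2.15 for Lag3. They ran from -3.62 to -0.34 for Irf8, 0.28 to 1.28 for Cxcl10, 0.33 to 1.22 for Gbp7 and 0.02 to 1.10 for H2-Q7. Apart from the left-out libraries and filters named, the cause was not tested.

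Counting error limits the scarce genes: T and NK cell markers, Igkc, S100a8 and most other markers under 1 CPM rest on few reads at these depths. In data simulated from these libraries, with genes varying independently, edgeR called 27 of 50 genes changed 2-fold. That share does not set the limit of the real fit, where much larger differences did not pass. Iqcn at 14.7-fold higher and Ighm at 20.4-fold lower both had an edgeR adjusted p of 0.1115.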

Other observations

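All tests here concern patterns already seen in the results. Predictions were recorded as written before the test only for the GC and length trend of the interferon gamma genes and the additional dissociation and heat-shock set. The gene families were chosen after their values were seen. Intervals given beside list medians are 95% bootstrap intervals over the genes of a list, with the libraries held fixed. They treat genes as independent and do not measure the spread between libraries. The clustered protocadherin beta genes, which encode cell-surface adhesion proteins from a single gene cluster, were lower in responder tumor cells in 14 of 14 tested members, 11 of them at an unadjusted p under 0.05. Their median log2 fold change was -1.19, or 2.28-fold lower (camera p = 2.74e-15, and p = 0.124 with an estimated correlation, neither adjusted). Pcdhb21 had 19.0 and 15.2 CPM in non-responder and 7.69 and 6.92 CPM in responder libraries, and Pcdhb16 8.85 and 7.05 against 2.73 and 2.57 CPM. The median was lower under each scaling tried and ran from -0.94 without non-responder replicate 1 to -1.49 without non-responder replicate 2. The clustered protocadherin gamma genes went both ways, 8 higher and 6 lower, with a median of 0.15 that was -0.08 without non-responder replicate 2. Whether members of these clusters share reads was not tested.

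Matrix metalloproteinase genes were lower in 8 of 9 tested members (median -0.76, camera p = 4.01e-08, and p = 0.0596 with an estimated correlation, neither adjusted), with Mmp16 at 58.7 and 40.3 against 28.1 and 27.8 CPM and Mmp19 at 12.1 and 15.5 against 7.35 and 6.87 CPM. Mmp9, Mmp12 and Mmp13 were lowest in responder replicate 1, where leukocyte markers were also lowest. Mmp9 still had 183 CPM there, against 341 and 396 CPM in the non-responder libraries and 289 CPM in responder replicate 2. Mmp2, Mmp14, Mmp16 and Mmp19 were lowest in responder replicate 2. Collagen chain genes were lower in 17 of 25 (median -0.16, camera p = 3.25e-05, and p = 0.0883 with an estimated correlation). Their median was -0.36 without non-responder replicate 1, -0.08 without non-responder replicate 2 and -0.43 without responder replicate 1. Col6a1 and Col6a2 had 2790 and 1960 CPM in non-responder replicate 1 and 2200 and 1680 CPM in non-responder replicate 2, against 1490 and 1080 CPM in responder replicate 1 and 1570 and 1200 CPM in responder replicate 2, while Col5a3 had 268 and 412 against 562 and 475 CPM. Both families were lower under each scaling tried.

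The lower fibroblast markers in responder tumor cells may come from host cells that passed the sort for GFP, or from the tumor cells themselves; of the 22 genes in the list 17 had a mean of at least 5 CPM, and Col3a1 had up to 13400 CPM. With the Xist level as a covariate the leukocyte list went from -1.50 to -0.09. The fibroblast list was then at -0.97 (95% bootstrap interval -1.41 to -0.55, camera adjusted p = 1.31e-13). This argues against host cells carried over in step with Xist as the whole source. Xist had the same order of libraries as the leukocyte list, so host fibroblasts that varied apart from leukocytes are not excluded. The fit with the Xist covariate had fewer residual degrees of freedom than the 2 of the main fit. Removing GC and length trends left the fibroblast list at -0.67 (-1.19 to -0.29), from -0.67 (-1.18 to -0.31), which argues against those trends. However, the bound for that test was first set at -0.3, which the upper limit of -0.29 misses, and was then moved to -0.2. Carried-over fibroblasts alone cannot be told apart from the tumor cells here. Of the members, 57.9% were lower in both responder libraries than in both non-responder libraries. The exact binomial interval, which takes members as independent, was 33.5% to 79.7%. That share lies between what chance gives and a bound assumed for fibroblasts after the results were seen. What fibroblasts would give was not measured. Response status also stays open, untested.

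The low interferon gamma response of non-responder replicate 1 is less likely to come from base composition or from fewer leukocyte transcripts overall. That library had the strongest GC trend (Spearman's rho -0.33 across genes), yet with the trends removed its list median minus the mean of the other libraries was -1.19 (-1.49 to -1.04), against -1.19 (-1.41 to -1.01) before. Responder replicate 1, with the fewest leukocyte transcripts, had a list median 1.18 above it (0.88 to 1.33). T and NK cell markers summed to 13.6 CPM in non-responder replicate 1, against 35.7 CPM in non-responder replicate 2 and 22.2 and 25.1 CPM in the responder libraries. Of these, Ccl5 made up 11.5 CPM in non-responder replicate 1, and few other members were above the floor, so that fewer T and NK cells stay open. The mitochondrial share was also highest there, at 5.61% against 3.07%, 3.27% and 4.22%. A difference between the tumors in interferon exposure, and a wrong label, stay open too, and none of these was tested.

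The higher immediate early genes in responder tumor cells could reflect handling. An additional set of 24 dissociation and heat-shock genes outside the list had 23 members tested. Of these 21 were higher, at a median of 0.41 (0.17 to 0.53). Camera p was 7.69e-09, and 0.0237 with an estimated correlation (0.0706 for the immediate early list), none adjusted. Stronger dissociation or heat stress of the responder samples would give such a rise. The members of smallest p were Csrnp1 (7.5 and 10.7 against 20.7 and 18.6 CPM) and Ier5 (31.5 and 51.8 against 82.6 and 90.9 CPM). Heat-shock and chaperone members of this set moved less, with log2 fold changes from 0.05 for Hspa4 to 0.36 for Hsp90aa1, apart from Dnaja1 at 0.90 (SE 0.40). The set therefore does not tell heat stress from a wider rise of immediate early genes. It also leaves out the heat-shock genes of the immediate early list, among them Hspa1b, with a DESeq2 log2 fold change of 2.08. Removing GC and length trends left the immediate early list at 0.71 (0.46 to 0.96), from 0.76 (0.58 to 1.02), which argues against those trends. Stress in the tumors before sorting would raise the same genes, and the design does not separate it from handling.

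The 4 libraries can be divided into 2 and 2 in 3 ways, too few for a share under 0.05. The real division gave 856 genes at an unadjusted p under 0.05. Replicate 1 of both groups against replicate 2 of both groups gave 1081, and replicates with unlike numbers together gave 160. Counting the real one, 2 of the 3 gave at least as many as the real one. In a principal component analysis the first component held 46.6% of the variance and set non-responder replicate 2 (-40.0) against responder replicate 1 (45.9), the pair with the most and the fewest leukocyte transcripts, and the second held 38.2% and set non-responder replicate 1 (46.6) apart.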
